A study of Mus musculus with 24 samples.

How the data were processed

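Total RNA of liver and epididymal white adipose tissue (EWAT) from male C57BL/6J mice was profiled on Illumina mouse bead arrays 48 hours after an intraperitoneal injection of SOX6-specific or control gapmer antisense oligonucleotides. Per the labels, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I treatment, checked on a Bioanalyzer, and turned into biotinylated cRNA with the Ambion MessageAmp kit. The 24 arrays lie on 4 chips of 6 arrays each, and each chip holds both treatments in both tissues. The authors ran GenomeStudio, of a version the labels do not state. The deposited intensity values are background-subtracted probe signals that were not normalized between arrays, and between 25.7% and 37% of the probes on an array lie below 0. A detection p-value of each probe against the negative controls of its array was deposited beside each signal. The authors' processed values are on the log2 scale. They equal the logarithm of the signal minus the lowest signal of its array plus a constant near 1, quantile normalized over all 24 arrays of both tissues. This was checked on the values, with a largest difference of 5.0e-09 log2 units.

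Of the 45281 probes, 34885 are paired with 1 gene by the platform's annotation, 18 with several genes and 10378 with none, and 34807 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez ID. Signals of each tissue were background corrected with the normal-exponential model from the detection p-values, quantile normalized with an offset of 16 and log2 transformed (neqc of limma 3.58.1, R 4.3.3). Repeat arrays of the same animal and tissue were averaged, so that n is 4 animals per treatment and tissue. A probe counted as detected in a tissue when its detection p-value was under 0.05 in at least 3 animals, and a gene was represented by its detected probe with the highest mean. Differences between SOX6 and control oligonucleotide were tested with limma's moderated test (lmFit and eBayes with an intensity trend, two-sided), adjusted by Benjamini-Hochberg with a threshold of 0.05 over the genes of a tissue. Standard deviations are between animals, standard errors and 95% intervals come from limma, and fold changes are SOX6 minus control oligonucleotide.

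The comparisons, the named-gene rule, 28 gene lists and 20 cell type marker lists with 1030 members in all, 938 of which have a named probe, were chosen before the data were examined. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of the tissue. An estimated correlation and the self-contained test fry (statmod 1.5.0 for the mixed models) were alternatives. For a score per animal, the members of a list were centred on their mean over the 8 animals and averaged, and scores were compared by an exact two-sided permutation test, whose smallest possible p with 4 animals against 4 is 0.0286. Sox6 was tested the same way with every probe of the gene. Genes were named by this rule: every Sox6 probe; up to 10 genes per direction with the largest change among those past the threshold whose animals did not overlap between treatments, filled up to 5 per direction with the smallest p among genes that did not pass; the 3 members with the smallest p from each shifted list, in its direction; 2 members with the smallest p from each of the lists of adipogenic regulators, mature adipocyte genes, 3 kinds of Wnt genes, fatty acid and triglyceride synthesis, cholesterol synthesis and lipoprotein metabolism; and Pparg, Cebpa, Mest and Axin2 in EWAT.

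The difference in response between the tissues was tested as an interaction after all 24 arrays were normalized together. Fold changes of the tissues were correlated across genes, with the same split of the animal labels permuted in both tissues for the p. Whether a label stands for the same animal in both tissues is not settled by the values. The 8 animals were also split in all 35 ways into 4 against 4. This was done for the counts of genes, lists and interaction genes past the adjusted threshold in the main fits, and for gene span. Counts at an unadjusted p, shares of genes without overlap and counts under the alternatives were not split. The values by chance beside them give no spread over animals. Gene spans are the distance from start to end of a gene in GRCm38.p6. The alternatives were other background corrections and normalizations, the authors' values, chip as a fixed term with the animal as a random block, unaveraged arrays, 1 array per animal, the replicate number as a block, array weights, other detection filters, the mean of a gene's probes, other variance models, a threshold of 0.1, and leaving out each animal in turn. Leaving out single EWAT samples with genes of other tissues, principal components as covariates, and leaving out genes that span over 200 kb were added after the data were seen, as were lists of ciliated cell, kidney, epithelial cell and fasting-induced liver genes. The procedure was tested on simulated data made by adding changes to 50 genes of each size. In liver, with 8731 genes, it recovered 56% of the changes of 0.5 log2 units and 96% of those of 1 log2 unit, and 4.9% of its calls were false. In EWAT, with 10935 genes, it recovered 14% and 64%, and 3.5% of its calls were false. With no change simulated it called 2 genes in liver and 0 in EWAT by limma, and no list in either tissue. The simulated genes varied independently of each other, so the simulation cannot show how often camera calls lists of correlated genes. In the measured data the splits other than the real one called a median of 6 lists in liver and 7 in EWAT. The number of animals limits the precision. Serum triglycerides and cholesterol were not analysed here, and probes without a gene name were used only for a separate count. Figures were drawn with matplotlib 3.10.9.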

Results

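Gene expression was measured in liver and EWAT of male C57BL/6J mice that had received gapmer oligonucleotides against Sox6, which encodes a transcription factor of the SOX family, or control gapmer oligonucleotides 48 hours earlier. Gapmers are antisense oligonucleotides that direct cleavage of the RNA they pair with. Each tissue was taken from 4 control animals and 4 animals given the SOX6 oligonucleotide, here C1 to C4 and S1 to S4. Liver was measured on 14 arrays and EWAT on 10. Between 32.9% and 36.4% of the probes were detected on a liver array and between 41.5% and 45.9% on an EWAT array. Repeat arrays of an animal correlated across probes at Pearson r of 0.992 to 0.995. The standard deviation of a single array was 0.123 to 0.153 log2 units, against a median standard deviation between animals of 0.177 in liver and 0.231 in EWAT. The tissues carried their own marker genes: the median log2 level of 19 hepatocyte genes was 13.58 to 13.92 in the livers and 4.37 to 4.59 in the EWAT samples, and that of 21 mature adipocyte genes was 4.52 to 4.83 in the livers and 9.32 to 10.17 in the EWAT samples.

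The target itself, Sox6, was measured by 5 probes, of which a single probe rose above background. In EWAT this probe was detected on all 10 arrays. It averaged 5.91 ± 0.34 (SD, n = 4) in control animals and 5.34 ± 0.37 (SD, n = 4) after the SOX6 oligonucleotide. The log2 fold change was -0.57 (SE 0.23, 95% interval -1.10 to -0.05), with an exact permutation p of 0.0857. It corresponds to 67.3% of the control value, with the added offset still in both values. The offset compresses this ratio, so 67.3% overstates the share of the signal above the offset that was left. The 4 control EWAT samples read 6.14, 6.19, 5.45 and 5.85 and the 4 treated ones 5.54, 5.12, 5.74 and 4.94, so that C3 lay below S1 and S3. Within the 4 chips the EWAT difference was -0.27, -0.44, -0.84 and -0.50. With chip as a fixed term it was -0.57, with limma's unadjusted p of 0.0282 from arrays that were not averaged. In liver Sox6 lay close to background, detected on 7 of 8 control arrays and on 2 of 6 treated ones. It averaged 4.98 ± 0.20 in control livers and 4.83 ± 0.09 in treated livers (SD, n = 4 each, exact permutation p = 0.229), a log2 fold change of -0.15 (SE 0.13, 95% interval -0.44 to 0.13). Within the 4 chips the liver difference was -0.07, -0.23, -0.07 and -0.20, and with chip as a fixed term it was -0.16, with limma's unadjusted p of 0.323. The other 4 Sox6 probes were detected on 0 of the liver arrays and 0 of the EWAT arrays. A lower Sox6 level in the treated animals therefore did not pass the exact test in either tissue. In EWAT the Sox6 difference was -0.27 without S2 and S4, -0.86 without C3 and S3, -0.52 without these 4, which leaves S1 as the single treated animal, and -0.21 with the first 2 principal components as covariates. Those 4 samples are the ones with high levels of genes of other tissues.

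**Figure D1:**
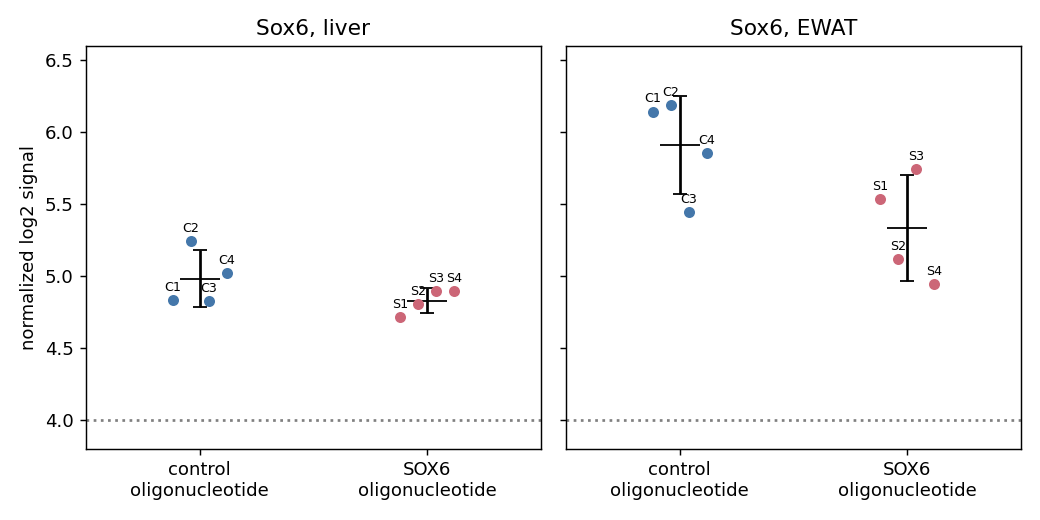
Normalized log2 signal of the highest Sox6 probe in each of the 8 animals, by treatment, in liver (left) and EWAT (right). Points are animals, bars are means with their standard deviations, and the dotted line is the log2 of the offset; the treated EWAT samples average 5.34 and the control samples 5.91, with S1 and S3 above C3.

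In liver, the question was which genes differ 48 hours after the SOX6 oligonucleotide. Of the genes that passed, 19 fell and 2 rose. Among the genes that fell were Ptprk, a receptor-type tyrosine phosphatase, which fell 2.82-fold from 9.26 ± 0.09 to 7.76 ± 0.36 (SD, n = 4 each, limma adjusted p = 0.00209), and Fabp5, a fatty acid binding protein, which went from 7.19 ± 0.56 to 5.71 ± 0.27 (SD, n = 4 each, limma adjusted p = 0.0441). Fhit, a hydrolase of diadenosine triphosphate, was detected on all 8 control arrays and on 0 of the 6 treated arrays, at least 1.92-fold lower (limma adjusted p = 0.0014). Ndufv1, a subunit of respiratory complex I, and Abcf1, an ATP-binding cassette protein that acts in translation, fell 2.37-fold and 2.31-fold.

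These 21 genes were among 8731 tested by limma. In each of them the 4 treated livers lay on one side of the 4 control livers, a separation seen in 5.9% of all genes tested and in 2.86% by chance. The unadjusted p was under 0.05 for 868 genes, against 437 by chance, with 457 of them lower and 411 higher, and under 0.01 for 159 lower and 120 higher genes. This share and these counts were not taken over splits of the animals, so how far chance can move them is not known. The median log2 fold change over all genes was 0.004. Ptprk had a log2 fold change of -1.49 (SE 0.15), Fabp5 of -1.48 (SE 0.25), Ndufv1 of -1.24 (SE 0.12) and Abcf1 of -1.21 (SE 0.11). Abcf1 also read -0.87 and -1.08 with its other 2 detected probes, whereas the other 2 probes of Ptprk read -1.03 and 0.00. Wfdc2, a secreted protein with a whey acidic protein core, had a log2 fold change of -1.35 (limma adjusted p = 0.00469), Atg16l2, a relative of an autophagy protein, of -1.22 (0.00469) and Sugct, a transferase of coenzyme A in glutarate breakdown, of -1.02 (0.00522). The drug-conjugating enzymes Ugt1a6b and Ugt1a6a had log2 fold changes of -0.97 and -0.95 (limma adjusted p = 0.0313 and 0.0441), and the other 2 detected probes of Ugt1a6a read -0.09 and -0.76. These 2 genes share most of their sequence, so their probes are not independent measurements. Fdps, which makes farnesyl diphosphate for sterol synthesis, had a log2 fold change of -0.48 with its highest probe (limma adjusted p = 0.0313) and of -1.53 with its other detected probe. The remaining 8 genes that fell ranged from -0.94 to -0.70.

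The 2 genes that rose in liver were Ugt2b1, another UDP-glucuronosyltransferase, with a log2 fold change of 0.65 (limma adjusted p = 0.0359), and Pcsk4, a proprotein convertase, with 0.64 (limma adjusted p = 0.0449), which its other 3 detected probes gave as 0.91, 0.66 and 0.47. The next genes in that direction did not pass: Gmfg at 0.60 (limma adjusted p = 0.0626), Ngef at 0.59 (0.0626) and Klhl24 at 0.35 (0.0977). Each of the 21 genes had its pooled sign within each of the 4 chips. The lack of overlap between the same animals largely fixed this in advance, so it adds no separate support. With chip as a fixed term and the animal as a random block limma called 110 genes, among them the same 21. That fit used arrays that were not averaged, and without the chip term it called 99. The higher count thus came mostly with the unaveraged arrays, which add degrees of freedom but no animals. Without C2, and likewise without S3, it called 12.

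**Figure D2:**
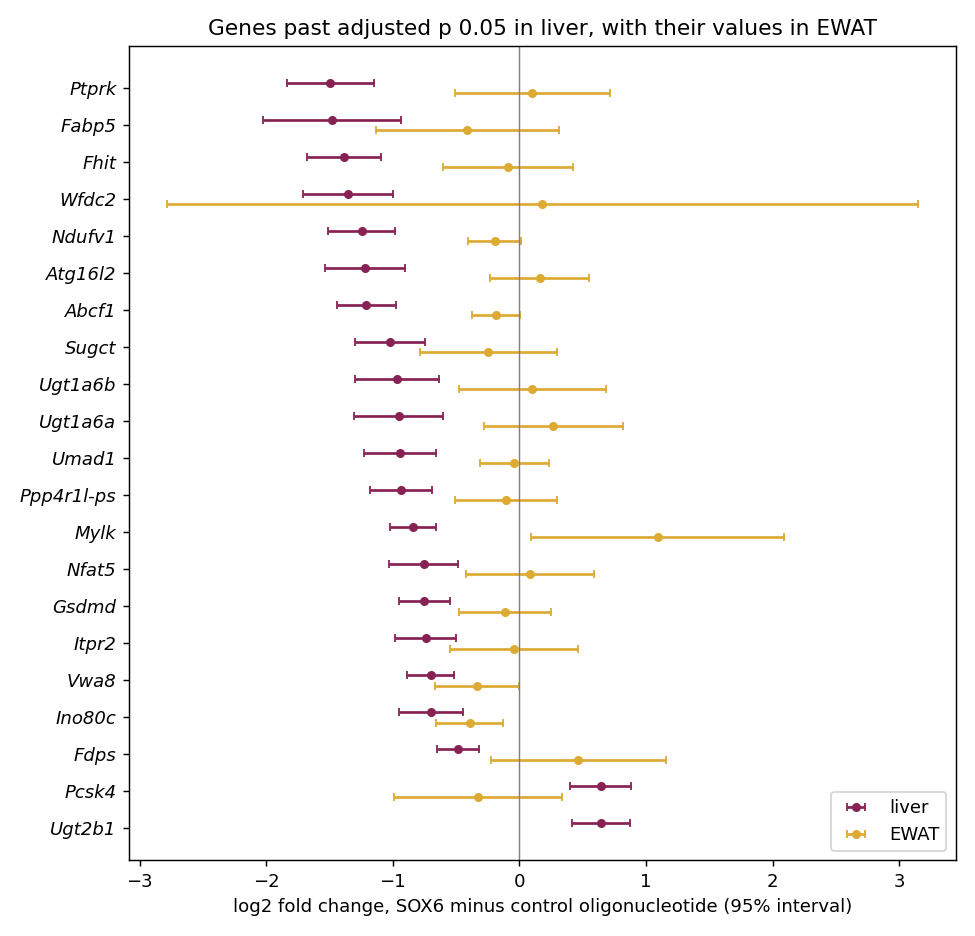
Log2 fold change (SOX6 minus control oligonucleotide) with its 95% interval for the 21 genes past an adjusted p of 0.05 in liver, with the liver value in purple and the EWAT value in yellow. In liver 19 genes lie below 0 and 2 above, from Ptprk at -1.49 to Ugt2b1 at 0.65, and 20 of them were also measured in EWAT.

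Among the gene lists, genes of lipid synthesis read lower in treated livers and genes of the circadian clock read higher. Of 21 measured genes of fatty acid and triglyceride synthesis 17 had a negative fold change, with a median of -0.37 (camera adjusted p = 3.07e-06, and adjusted p = 0.606 with an estimated correlation). Of 13 clock genes 12 had a positive fold change, with a median of 0.40 (camera adjusted p = 1.29e-04, and adjusted p = 0.606 with an estimated correlation). Of 17 genes of cholesterol synthesis 14 were negative, with a median of -0.16 (camera adjusted p = 0.00206, and adjusted p = 0.655 with an estimated correlation). Of 21 extracellular matrix genes 19 were negative, with a median of -0.16 (camera adjusted p = 0.00366, and adjusted p = 0.655 with an estimated correlation).

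No member of the fatty acid and triglyceride list passed over all genes by limma, and 6 were lower when adjusted over the list alone. Acacb, which makes malonyl-CoA, read -0.91 (limma adjusted p = 0.0977), Acss2, which activates acetate, read -0.69 (0.0778) and Acly, which makes cytosolic acetyl-CoA from citrate, read -0.61 (0.146), and in each of them the treated livers all lay below the control livers. In cholesterol synthesis Fdps fell, and 2 genes were lower when adjusted over the list alone. Pmvk, phosphomevalonate kinase, read -0.68 (limma adjusted p = 0.146) and Tm7sf2, a sterol reductase, read -0.25 (0.382). Among the clock genes none passed, over all genes or when adjusted over the list alone. The period gene Per2 read 0.69 (limma adjusted p = 0.385), the clock output gene Dbp 0.42 (0.28) and Tef 0.40 (0.351). No matrix gene passed either, and 0 did when adjusted over the list alone: Col4a2 and Col18a1, chains of basement membrane collagens, read -0.63 and -0.24, and the membrane-bound protease Mmp14 read -0.58 (limma adjusted p = 0.397, 0.342 and 0.251).

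Scored per animal, the clock list was higher in all 4 treated livers than in any control liver, by 0.46 (exact permutation p = 0.0286, the smallest possible), with control liver C1 at -0.76 and the other 3 control livers at -0.09 to 0.02, and by 0.28 without C1. The periportal hepatocyte list separated the animals as well, by 0.16 (exact permutation p = 0.0286), so 2 of 35 lists did so, against 1 by chance. The fatty acid and triglyceride list differed by -0.34 (exact permutation p = 0.114), the cholesterol list by -0.18 (exact permutation p = 0.114) and the matrix list by -0.18 (exact permutation p = 0.143). Within the 4 chips the fatty acid and triglyceride list differed by -0.19, -0.57, -0.50 and -0.22, the clock list by 0.66, 0.20, 0.21 and 0.61, the matrix list by -0.06, -0.16, -0.16 and -0.31, and the cholesterol list by 0.003, -0.37, -0.30 and -0.25. In all, 4 of 35 lists passed with the preset correlation and 0 with an estimated one. Without C3 the median of the fatty acid and triglyceride list was -0.23 (camera adjusted p = 5.51e-05) and that of the cholesterol list -0.12 (0.0426), and without C1 that of the clock list was 0.26 (7.67e-04). Over all 8 animals left out in turn the medians ranged from -0.38 to -0.23 for the fatty acid and triglyceride list, from -0.20 to -0.12 for the cholesterol list, from 0.26 to 0.49 for the clock list and from -0.22 to -0.11 for the matrix list. Without C1 the matrix list had a median of -0.14 (camera adjusted p = 0.179) and its score differed by -0.09 (exact permutation p = 0.257). C1 scored 0.38 on the matrix list, 0.30 on stellate cell and fibroblast genes, 0.45 on endothelial genes and 0.74 on macrophage genes, and the other 3 control livers at most 0.10, 0.13, -0.14 and -0.06.

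**Figure D3:**
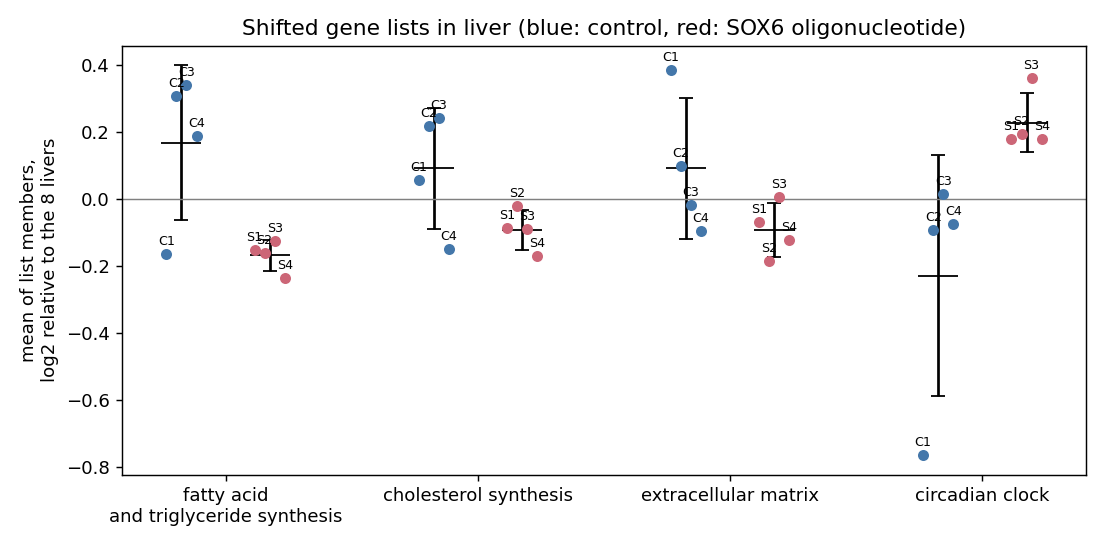
Mean of the members of 4 gene lists in each liver, in log2 units relative to the mean of the 8 livers, with control animals in blue and animals given the SOX6 oligonucleotide in red. Bars are means with standard deviations over 4 animals; the clock list reads -0.76 in C1 and 0.18 to 0.36 in the treated livers.

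Other genes of adipocyte, Wnt and lipoprotein biology did not pass in liver. Among adipogenic regulators Klf15 read 0.52 and Bmp4 -0.46, and among mature adipocyte genes Pck1, the key enzyme of gluconeogenesis, read 0.70 and Gpd1 -0.38 (limma adjusted p = 0.446, 0.358, 0.373 and 0.472). Among Wnt genes, the Wnt-modifying enzyme Porcn read -0.29, the receptor Fzd5 0.30, the antagonists Dkk3 and Ctnnbip1 0.48 and 0.31, and the target gene Ppard 0.36, with limma adjusted p of 0.358 to 0.425. Among lipoprotein genes Apom, an apolipoprotein of high-density particles, read -0.35 and the lipase maturation factor Lmf1 -0.36 (limma adjusted p = 0.251 and 0.271). None of the lists of adipogenic regulators (median -0.06 over 11 genes), Wnt ligands, receptors and transducers (-0.05 over 23), Wnt antagonists (0.03 over 12), Wnt target genes (0.02 over 14) and lipoprotein metabolism (-0.03 over 23) was shifted, with camera adjusted p from 0.468 to 0.93. The mean of the adipogenic regulators was 0.04 and that of the Wnt target genes -0.02, opposite in sign to their medians and on the side of the test.

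In EWAT, the question was which genes of fat differ after the SOX6 oligonucleotide, and by the study's title whether adipogenic and Wnt genes do. No gene passed by limma. Some fat samples carried high levels of genes that belong to other tissues. Spink8 and Defb42, genes of the epididymis, read 14.20 and 13.00 in S2 and 13.82 and 12.68 in S4, and at most 4.98 and 5.64 in the other 6 samples. Cldn2 and Cdh16, genes of transporting epithelia, read 10.04 and 10.33 in C3 and 9.97 and 10.53 in S3, and at most 5.08 and 6.65 elsewhere, and Tekt1, a gene of cilia, read 8.54 in both and at most 4.36 elsewhere.

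Of 10935 genes tested in EWAT, 0 passed an adjusted p of 0.05 or of 0.1 by limma, and 546 had an unadjusted p under 0.05, against 547 by chance. The smallest adjusted p was 0.842. Groups did not overlap in 2.78% of the genes, against 2.86% by chance. The genes with the smallest p and no overlap were Sorl1, a sorting receptor, at 0.80, Cbr2 at 0.60, Adh5 at 0.42, Aimp1 at 0.34 and Prdx2, a peroxiredoxin, at 0.30, and in the other direction Hsf3 at -0.78, Gmds at -0.75, Tenm4 at -0.57, Agt, which encodes angiotensinogen, at -0.54 and Bag4 at -0.48, each with a limma adjusted p of 0.842. Adh5 read -0.11 with its other detected probe, and Prdx2 0.05 and -0.14 with its other 2. Without the 4 fat samples C3, S2, S3 and S4, which leaves 3 control animals and 1 treated animal, limma called 0 genes, with 174 at an unadjusted p under 0.05, and with the first 2 principal components as covariates 0 genes, with 333.

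**Figure D4:**
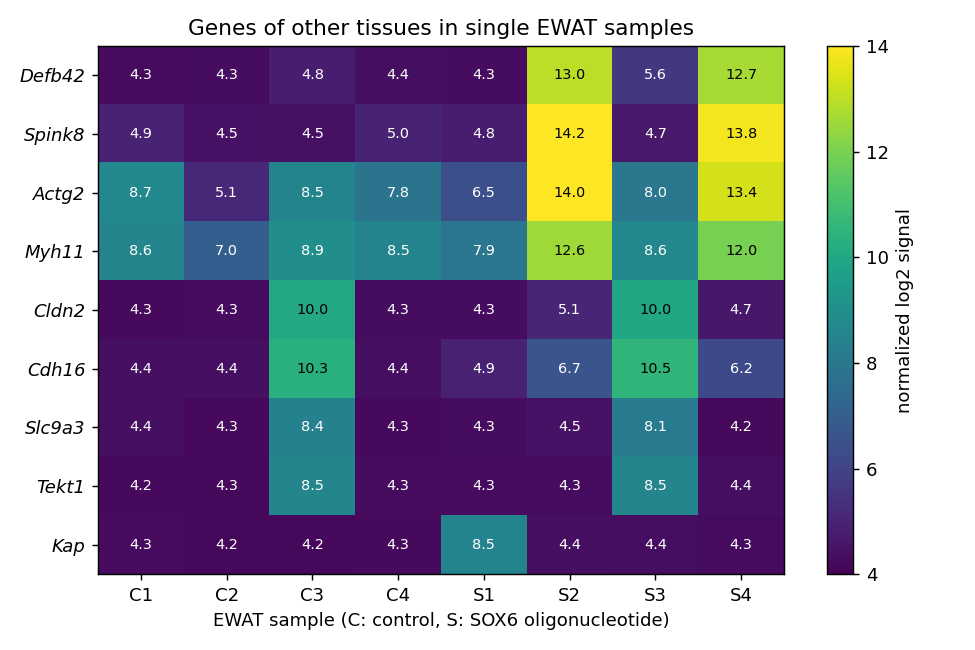
Normalized log2 signal of 9 genes of other tissues in the 8 EWAT samples, 4 from control animals (C) and 4 from animals given the SOX6 oligonucleotide (S). Defb42 and Spink8 stand out in S2 and S4, Cldn2 and Tekt1 in C3 and S3, and Kap in S1, where it reads 8.53.

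Genes of the adipogenic program had no passing member. Pparg, the main regulator of adipocyte differentiation, averaged 12.03 ± 0.21 and 11.63 ± 0.46 (SD, n = 4 each, limma adjusted p = 0.842), a log2 fold change of -0.41 (95% interval -0.88 to 0.07), and its other 2 detected probes read -0.10 and -0.18. Cebpa, its partner in differentiation, read -0.23 (95% interval -0.56 to 0.09) and Mest, a gene linked to fat expansion, -0.33 (95% interval -2.45 to 1.79) and -0.64 and -0.52 with its other 2 detected probes. Without the 4 samples with genes of other tissues Pparg, Cebpa and Mest turned to 0.18, 0.04 and 1.08, and Pparg read -0.18 without S2 and S4, -0.42 without C3 and S3 and -0.044 with 2 principal components. The list of adipogenic regulators had a median of -0.09 over 24 genes (camera adjusted p = 0.824, on the side of the median) and a mean of 0.08, with Egr2 at 1.11 and Zfp467 at -0.31.

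Of 21 mature adipocyte genes 17 had a negative fold change, with a median of -0.21 (camera adjusted p = 0.0265, and adjusted p = 0.669 with an estimated correlation), and 0 passed when adjusted over the list alone by limma. The lipid droplet protein Plin1 read -0.41, the adipokine Retn -0.50 and the receptor Acvr1c -0.55, each with a limma adjusted p of 0.842. The list score was -0.25 in S2, -0.29 in S3 and -0.13 in C3, and 0.02 to 0.31 in the other 5 samples. The median was -0.15 without S2 and S4 (camera adjusted p = 0.067), -0.17 without C3 and S3 (0.0134) and -0.050 with 2 principal components (0.693). It was -0.052 without C3, S2, S3 and S4, which leaves S1 as the single treated sample. Of 33 nuclear genes of the respiratory chain 28 were negative, with a median of -0.08 (camera adjusted p = 0.0467, and adjusted p = 0.68 with an estimated correlation), among them Ndufb8 at -0.24, Cox5a at -0.22 and Ndufv1 at -0.20, and 0 passed when adjusted over the list alone. Its median was -0.11 without S2 and S4 (camera adjusted p = 0.0245), -0.052 without C3 and S3 (0.609), 0.00073 without C3, S2, S3 and S4, and -0.080 with 2 principal components (0.0586).

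Genes of macrophages, smooth muscle, fibroblasts and the cell cycle read higher in treated EWAT at the preset correlation, whereas 13 of 20 endothelial genes were negative (median -0.12, camera adjusted p = 0.477). Of 17 macrophage genes 15 had a positive fold change, with a median of 0.49 (camera adjusted p = 4.34e-04, and adjusted p = 0.669 with an estimated correlation). The complement gene C1qb read 0.79, the scavenger receptor Cd163 0.72 and Timd4 0.61, each with a limma adjusted p of 0.842. The score of control sample C4 was -0.95 against -0.03 to 0.12 in the other control samples, and without C4 the median was 0.19 (camera adjusted p = 0.168). The median was 0.70 without S2 and S4 (camera adjusted p = 1.59e-09), 0.49 without C3 and S3 (0.0012) and 0.61 with 2 principal components (4.45e-07), at the preset correlation. Without C3, S2, S3 and S4 it was 0.88, with S1 as the single treated sample and C4 among the controls. The estimated correlation of the macrophage genes was 0.625, far above the preset 0.01, so these p-values count correlated genes as nearly independent. Of 13 smooth muscle and pericyte genes 10 were positive, with a median of 0.78 (camera adjusted p = 0.00858, and adjusted p = 0.669 with an estimated correlation), among them Myh11 at 2.03 (95% interval -0.23 to 4.29), Acta2 at 0.99 and Smtn at 0.94. The list score was 1.32 in S2 and 1.27 in S4, the samples with Spink8 and Defb42, and -0.86 to -0.16 in the other 6. The median of the smooth muscle list was -0.09 without S2 and S4 (camera adjusted p = 0.503), 1.27 without C3 and S3 (0.00289), -0.15 without C3, S2, S3 and S4, and -0.19 with 2 principal components (0.207). Of 17 stellate cell and fibroblast genes 14 were positive, with a median of 0.20 (camera adjusted p = 0.0467, and adjusted p = 0.669 with an estimated correlation), with the muscle filament gene Des at 1.55, Ngfr at 0.59 and Thy1 at 0.45. Without S2 and S4 Des and Ngfr turned to -0.11 and -0.03 and the median of the list was 0.11 (camera adjusted p = 0.104). The median was 0.23 without C3 and S3 (0.0134), 0.15 without C3, S2, S3 and S4, and 0.078 with 2 principal components (0.386). Of 23 cell cycle genes 18 were positive, with a median of 0.14 (camera adjusted p = 0.0219, and adjusted p = 0.669 with an estimated correlation), with Tk1 and Cdc20 at 0.47 and Birc5 at 0.36, while Tk1 read -0.24 with its other detected probe and Cdc20 0.21 and -0.01 with its other 2, and the list score was 0.16 in S3, 0.08 in C3 and 0.08 in S2. The median of the cell cycle list was 0.13 without S2 and S4 (camera adjusted p = 0.00267), 0.16 without C3 and S3 (0.0134) and 0.085 without C3, S2, S3 and S4. It was 0.055 with 2 principal components (camera adjusted p = 0.0586) and 0.15 with chip as a fixed term and the animal as a random block (0.0639). In these 4 lists 0 genes passed when adjusted over the list alone.

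Wnt genes had no passing member in EWAT. Rspo3, which amplifies Wnt signals, read 1.30 and the ligand Wnt5a -0.40, the antagonists Tle2 and Nkd1 0.55 and 0.39, and the target genes Bmp4 and Axin2 0.43 and -0.61 (limma adjusted p of 0.842 to 0.855), while Bmp4 read 0.01 with its other detected probe. The 3 Wnt lists had medians of -0.01 over 34 ligands, receptors and transducers, 0.19 over 17 antagonists and 0.04 over 15 target genes, with camera adjusted p of 0.759, 0.0771 and 0.477. The ligands, receptors and transducers had a mean of 0.04, on the side of the test. In lipid metabolism Fads2, a fatty acid desaturase, read 1.29 and Dgat1, which completes triglyceride synthesis, -0.41, Idi1 and Mvd of sterol synthesis -0.51 and -0.28, and Abca1 and Apoc2 -0.47 and -0.35, each with a limma adjusted p of 0.842, while Apoc2 read 0.27 with its other detected probe. Epithelial genes averaged 6.67 in C3, 7.39 in S2, 6.67 in S3 and 6.72 in S4, and at most 5.11 in the other 4 samples, so 3 of the 4 treated samples and 1 of the 4 control samples were high.

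Within the 4 chips the scores differed between treatments in EWAT by -0.23, -0.42, -0.13 and 0.16 for the mature adipocyte list, by 1.46, 0.23, 0.29 and -0.23 for the macrophage list, by -0.32, 0.49, 0.63 and 1.43 for the smooth muscle list, by 0.36, 0.31, 0.05 and 0.17 for the stellate cell and fibroblast list, by 0.15, 0.24, 0.19 and -0.08 for the cell cycle list, and by -0.08, -0.05, -0.16 and -0.03 for the respiratory chain list. In all, 6 of 44 lists passed with the preset correlation and 0 with an estimated one, and with C4 left out 1 list passed. Leaving out a single animal ended further camera calls, with these medians and adjusted p. The mature adipocyte list had -0.093 without C4 (0.297), -0.093 without S2 (0.0787) and -0.18 without S3 (0.138). The cell cycle list had 0.11 without C4 (0.159) and 0.11 without S3 (0.138). The respiratory chain list had -0.059 without C1 (0.481), -0.057 without C3 (0.151), -0.072 without C4 (0.197) and -0.041 without S3 (0.35). The stellate cell and fibroblast list had 0.060 without C4 (0.697), 0.061 without S3 (0.138) and 0.13 without S4 (0.16), and the smooth muscle list 0.55 without S4 (0.125). Over all 8 animals left out in turn the medians ranged from -0.30 to -0.093 for the mature adipocyte list, from 0.11 to 0.20 for the cell cycle list, from -0.14 (without C2, 1.54e-05) to -0.041 for the respiratory chain list, from 0.060 to 0.26 for the stellate cell and fibroblast list, from 0.41 to 1.08 for the smooth muscle list and from 0.19 to 0.68 for the macrophage list. Other ways of processing ended 3 of the calls, again with medians and adjusted p. The cell cycle list had 0.18 with 1 array per animal (0.0514), 0.11 with no detection filter (0.0797) and 0.12 with genes detected on every array (0.125). The respiratory chain list had -0.082 with all arrays normalized together (0.0508), -0.030 with array weights (0.447), -0.081 with genes detected on every array (0.0819) and -0.081 without the variance trend (0.0883). The stellate cell and fibroblast list had 0.30 with median scaling (0.0825), 0.23 with all arrays normalized together (0.0508), 0.12 with no detection filter (0.0906) and 0.20 without the variance trend (0.0746).

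The interaction asked whether the response differed between the tissues. Abcf1 and Fhit, which fell in liver, differed in their response between EWAT and liver. Normalized over all arrays together, Abcf1 had a log2 fold change of -1.10 in liver and -0.22 in EWAT, a difference of 0.88 (SE 0.13, limma adjusted p = 0.0443). Fhit had a fitted -1.80 in liver, which depends on the floor since it was not detected there after treatment, and -0.09 in EWAT, a difference of 1.71 (SE 0.26, limma adjusted p = 0.0443). Next were Atg16l2 at 1.31, Adam32 at -0.82, Ndufv1 at 0.92 and Ppp4r1l-ps at 1.13, which did not pass (limma adjusted p = 0.0506 to 0.0507). These 4 were named after their values were seen. Of 11413 genes tested, 2 passed, and 727 had an unadjusted p under 0.05, against 571 by chance. With the same label taken as the same animal in both tissues, which the values do not settle, and the animal as a block, limma called 0 genes, with 719 at an unadjusted p under 0.05, and with chip as a fixed term 13. It also called 0 without C1, C2, C4, S1, S3 or S4 in turn, with 526 to 1062 at an unadjusted p under 0.05.

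The last comparison asked whether genes moved the same way in both tissues. Across 8253 genes measured in both, the log2 fold changes correlated at a Pearson r of 0.0441 and a Spearman rho of 0.0408, and genes are not independent replicates. The permutation p over the 35 splits of the animal labels, split alike in both tissues, was 0.714. Of the 20 genes that changed in liver and were measured in EWAT, 11 had the same sign there. The 19 genes that fell in liver had a median of -0.95 there and of -0.04 in EWAT. Ino80c read -0.70 in liver and -0.39 in EWAT, and Mylk, a kinase of smooth muscle contraction, -0.84 in liver and 1.09 in EWAT. Neither passed in EWAT (limma's unadjusted p = 0.0079 and 0.0353). The smooth muscle list was high in EWAT samples S2 and S4 alone (scores of 1.32 and 1.27). No value of Mylk without these samples is given here, so its EWAT value cannot be read as an opposite response. Ino80c and Mylk were named after their values were seen. Without C3 the correlation turned to -0.037, and without the 4 EWAT samples with genes of other tissues to -0.016.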

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

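The splits for the counts of genes in liver and EWAT, every test on the source of the EWAT genes of other tissues, the exchange of C3 and S1, and the tests of collection time and of control liver C1 were chosen after the results were seen. The splits for the lists and for the interaction and the test of feeding were written down before their results were seen.

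A sample far from the other 3 of its group was found in 15 of 190 groups of 4 tested, where chance gives about 9.5. The value in each case is the gap to the nearest other sample divided by the range of the group. In liver it was 0.837 for Klhl24 (C3 low), 0.895 for Ptprk (S2 high), 0.842 for Fabp5 (S3 low), 0.833 for Mmp14 (S1 high) and 0.847 for Pck1 (S1 low). The score of the liver clock list had C1 low among the control animals (0.864) and S3 high among the treated animals (0.908). In EWAT it was 0.896 for Sorl1 (C1 low), 0.854 for Acvr1c (S4 low), 0.887 for Ndufb8 in the control animals (C2 low) and 0.834 in the treated animals (S4 high). It was 0.896 for C1qb (C4 low), 0.873 for Mest (S2 low), 0.87 for Axin2 (C4 low) and 0.864 for the score of the macrophage list (C4 low).

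The response of Fhit in EWAT minus that in liver was a fitted 1.71 log2 units and that of Abcf1 0.881, both by limma's test of the difference. The value of Fhit depends on the floor, since it was not detected in treated livers. Of the 35 splits of the animals 3 gave at least 2 genes with an interaction, so chance cannot be excluded, and the highest other split gave 272. That split set C1, C2, C4 and S1 against C3, S2, S3 and S4, which points to a structure of the EWAT samples. For the genes that changed in liver the real split gave 21 and the highest other 2, so that 1 of the 35 splits gave as many. That is the smallest share these splits can give, and the test was chosen after the results were seen. It argues against chance but cannot exclude it. Among 2095 detected liver probes without a gene name, which the comparisons did not use, 4 passed an adjusted p of 0.05 by limma, all lower after the SOX6 oligonucleotide.

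The EWAT samples C3, S2, S3 and S4 carried genes of other tissues, and the split that sets these 4 apart called 432 genes, which points to a structure of the samples. The labels called 0 genes by limma (546 at an unadjusted p under 0.05), so that all 35 of 35 splits gave as many and this count decides nothing, and for the lists chance cannot be excluded, since 21 splits gave at least 6 shifted lists, the highest other 13. Tissue of the epididymis or the deferent duct is a candidate source in S2 and S4, since Spink8 lay at least 8.83 log2 units above every other sample and the median of the smooth muscle list was -0.0909 without these 2 samples and 0.78 with them, although of 25 measured genes of the epididymis list, 13 of them detected on no EWAT array, only Spink8 and Defb2 (7.23 and 7.47) were over 1 log2 unit higher there and 3 were so in S3 (Defb20 at 7.29, Adam7 at 7.41 and Lcn8 at 6.86), so such tissue stays open in S3 too. Ciliated tissue of the efferent ducts is a candidate source in C3 and S3, where 31 ciliated cell genes lay a median of at least 1.49 log2 units above the highest other sample (Zmynd10, which gives this median, was detected on 2 arrays, so the floor limits the gap), 19 of them by over 1, with Tekt1 at 8.54 in both, and 3 of the 31 were detected on every EWAT array. Kidney tissue in S1 stays open. Of 27 kidney genes 2, Kap at 8.53 and Slc34a1 at 6.85, were over 1 log2 unit higher in S1 than in each other sample, too few to decide. Kidney list genes were not confined to S1. Keg1 read 7.01 in S1, 7.14 in C3 and 7.60 in S3, and at most 4.36 elsewhere, and Slc34a1 read 5.42 in C3 and 5.38 in S3. Kidney tissue in C3 and S3 was not tested. Exchanged labels of C3 and S1 cannot be told apart from chance dissection of neighbouring tissue. The exchange gives the same split with 432 genes whichever holds. An effect of the SOX6 oligonucleotide on these other tissues was not tested.

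The lipid synthesis lists read lower and the clock list higher in treated livers, but 29 of the 35 splits gave at least 4 shifted liver lists, the highest other 14, so chance cannot be excluded. A different time of tissue collection stays open. The 13 clock genes measured in both tissues had a mean log2 fold change of 0.0167 in EWAT (95% interval over genes -0.0818 to 0.115) and of 0.457 in liver. These genes thus showed no common rise in EWAT. The interval is over genes and not over animals, and members that move in opposite directions can cancel in a mean. The EWAT samples C3, S2, S3 and S4 also carried genes of other tissues, so the values do not decide about collection time. Control liver C1 alone is argued against for the fatty acid and triglyceride list. C1 scored -0.164 on it, inside the range of the treated livers (-0.235 to -0.124), and so worked against the difference. Leaving C1 out could only enlarge that difference. For the clock list the other control livers also lay below the treated livers, so C1 was not the only source of the difference. Without C1 the scores of the 2 lists differed by -0.447 and 0.278 (-0.336 and 0.457 with it). Without C1 the animals did not overlap in the fatty acid and triglyceride list (exact permutation p = 0.0286). That separation was gained by leaving out the 1 control liver that overlapped the treated ones. In the clock list the animals already did not overlap with C1 included. The same exact permutation p without C1 was therefore fixed in advance and adds nothing, and C1 carries part of the clock difference. For cholesterol synthesis the score differed by -0.194 without C1 and -0.183 with it, but the animals overlapped (exact permutation p = 0.171), so this list stays open. The highest camera adjusted p of these 3 lists without C1 was 0.000881 at the preset correlation. It decides little, since most splits gave as many shifted lists. A difference in feeding may contribute and stays open: fasting-induced liver genes had a median of 0.199, with 19 of 26 positive, and a mean of 0.167 whose 95% interval over genes reached from 0.0756 to 0.259. An effect of the SOX6 oligonucleotide itself on lipid synthesis stays open as well and was not tested apart from these.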

How the results depend on the processing

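The alternatives that leave out the EWAT samples C3, S2, S3 or S4, use principal components, or leave out genes over 200 kb were chosen after the data were seen; all others were planned. In liver, the 38 named genes kept their direction in all of 869 settings, with 64 falling behind the threshold and 26 passing it anew. Settings such as the variance model or the genes left out cannot move a fold change. Many of these genes were named because their animals did not overlap between treatments. Leaving out 1 animal can hardly turn the sign of such a gene, so the kept direction was partly fixed by the naming rule. The 4 shifted liver lists kept direction and call in 91 of 100 settings. In EWAT, 45 named genes did so in 1136 of 1160 settings and 6 lists in 116 of 168. EWAT had 0 genes past the threshold by limma in each setting run, with 174 to 1215 genes at an unadjusted p under 0.05 in the fits with 1 probe per gene. Both Sox6 fold changes stayed negative in each setting run. Signal over background limits Sox6 in liver. Of simulated changes of 0.5 log2 units 14% were recovered in EWAT and 56% in liver, with 4 animals per group in both.

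Liver genes past the threshold numbered 110 with chip as a fixed term and 99 with unaveraged arrays. They numbered 43 with the replicate number as a block, 36 with array weights, 34 at a threshold of 0.1, 13 without the variance trend, 7 without genes over 200 kb, and 12 (without C2) to 22 without 1 animal. The same 21 genes were among those called with chip, unaveraged arrays and array weights, and 19 of them with the replicate block. Shifted liver lists numbered 7 with median scaling and with the mean of a gene's probes, 8 with 1 array per animal, the replicate block, array weights or no detection filter, 5 to 9 without 1 animal (9 without C1, 7 without C3 or S1), and 0 with an estimated correlation and with fry. Liver Sox6 ranged from -0.20 to -0.06 without 1 animal.

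EWAT Sox6 was -0.567 with chip as a fixed term, -0.573 with unaveraged arrays, -0.572 with the replicate block and -0.712 with array weights. These fits give limma's unadjusted p (0.0282, 0.0373, 0.0487 and 0.0085) in place of an exact one. In the fits with chip and with unaveraged arrays, repeat arrays add degrees of freedom but no animals. It ranged from -0.73 to -0.44 without 1 animal. Shifted EWAT lists numbered 10 without C3 and S3, 1 (without C4) to 10 (without S1) without 1 animal, 2 without S3, and 0 with an estimated correlation and with fry. The interaction gave 0 genes with the animal as a block, 13 with chip and unaveraged arrays, 5 without the variance trend, and 0 to 2 without 1 animal. Abcf1 and Fhit were both called with chip and without the variance trend. Only 1 of these 2 genes was called with each tissue normalized alone, with no detection filter, without C3 and without S2. The correlation between the tissues was -0.0373 without C3 and -0.0163 without the EWAT samples C3, S2, S3 and S4. It ranged from -0.0373 to 0.126 without 1 animal. The hepatocyte level of liver minus EWAT was 9.60 with the authors' values and with no background correction, against 9.35.

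These EWAT values turned their sign. Without C3, S2, S3 and S4, a fit of 3 control animals against 1 treated animal that is assumed to vary like them, Des read -0.21, Myh11 -0.10, Acta2 -0.092, Smtn -0.15, Apoc2 0.011, Pparg 0.18, Cebpa 0.044 and Mest 1.08, the smooth muscle list -0.15 and the respiratory chain list 0.00073. Without S2 and S4, Des read -0.11, Ngfr -0.027, Acta2 -0.043, Smtn -0.11 and Mest 0.65, and the smooth muscle list -0.0909. With 2 principal components, Des read -0.28, Ngfr -0.071, Myh11 -0.19, Acta2 -0.19, Smtn -0.25, Cebpa 0.029 and Mest 0.67, and the smooth muscle list -0.19. Mest ranged from -1.09 to 0.53 without 1 animal, above 0 without C3 (0.014), C4 (0.025) and S2 (0.53), and Tk1 -0.29 with 1 array per animal. Except where a setting holds fewer genes or samples, the cause was not tested. Whether replicate numbers pair the animals stays open: residual correlations of same-numbered animals were -0.04 to 0.33 in liver (1 of 4 over 0.1) and -0.05 to 0.66 in EWAT (3 of 4), and -0.05 to 0.22 for the same label across tissues (2 of 8).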

Other observations

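The choice of the lists and genes named in this part and the test of cleavage of long precursors were taken up after their results were seen; the tests of chance, probe level and chip for gene span were written down before theirs.

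In liver, Fasn, the fatty acid synthase, read -1.08 and Pnpla3, a lipid droplet protein of lipogenic liver, -1.01 (limma adjusted p = 0.202 and 0.158). Pnpla3 averaged 4.69 in the treated livers, below Sox6 at 4.83, which lay close to background, so the floor limits its value. Among the clock genes Usp2 read 1.27 and Ciart 1.07, and Clock itself, the member with a negative value, -0.29. Genes of fatty acid oxidation and ketogenesis had a median of 0.12, with 15 of 23 positive (camera adjusted p = 0.0514), and all 6 measured mesothelial genes were negative, with a median of -0.24 (camera adjusted p = 0.0514). Interferon response genes had a median of 0.11, with 28 of 32 positive, respiratory chain genes 0.05, with 26 of 34 positive, and cell cycle genes 0.17, with 9 of 12 positive (camera adjusted p = 0.0722 each). Genes of glucose metabolism and insulin response had a median of 0.16 (camera adjusted p = 0.0953), periportal hepatocyte genes 0.03 (0.283), pericentral ones 0.01 with a mean of -0.03 and a test on the negative side (0.93), and targets of the xenobiotic receptors CAR, PXR and AHR 0.04 with a mean of -0.007 and a test on the positive side (0.93), with Ugt1a6a past the threshold. Macrophage genes had a median of 0.14 in liver (camera adjusted p = 0.443), and the acute phase list -0.05 with a mean of 0.009 and a test on the negative side (0.93).

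In EWAT, inflammatory genes of the NF-kB list had a median of 0.22, with 12 of 18 positive (camera adjusted p = 0.0633), and immediate early genes, which respond to handling and dissection, 0.23, with 12 of 19 positive (0.076). Extracellular matrix genes had a median of 0.09, with 21 of 34 positive (camera adjusted p = 0.076), and lipolysis genes -0.15, with 9 of 12 negative (0.0926). Of 11 measured SOX family genes 9 were negative, with a median of -0.18 (camera adjusted p = 0.159). Interferon response genes had a median of 0.005, with 15 of 30 positive (camera adjusted p = 0.477), and clock genes 0.03, with 8 of 14 positive, a mean of -0.03 and a test on the positive side (0.761). Fatty acid and triglyceride synthesis and cholesterol synthesis had medians of -0.17 and -0.19 in EWAT (camera adjusted p = 0.429 and 0.2).

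Genes with long genomic spans read lower in treated livers: 305 genes over 200 kb had a median log2 fold change of -0.08 and 8413 shorter genes one of 0.01, and 6 of the 19 genes that fell were over 200 kb (Fhit at 1612 kb, Sugct, Ptprk, Itpr2, Vwa8 and Mylk; Fisher's exact p = 3.22e-05 against 3.5% of the genes tested), while without genes over 200 kb 7 of the 15 genes still tested among the 21 passed. Fisher's test counts the genes as independent, which genes measured in the same animals are not, so its p overstates the evidence. Chance cannot be excluded for the difference of medians of -0.0892, since 2 of the 35 splits gave one as large, the highest other 0.0907. A lower probe level of long genes is argued against by differences of -0.0482, -0.132 and -0.194 in the 3 groups of genes with low, middle and high level, and a difference between chips by differences of -0.0444 to -0.145 within each chip. Cleavage of long precursor RNAs by the oligonucleotide outside its target may contribute and stays open: the difference was 0.00206 in EWAT, while the Spearman correlation of the fold change with span over all genes was -0.0343 in liver and -0.0341 in EWAT, and how much oligonucleotide reached either tissue was not measured here. An effect of lower Sox6 itself on these genes was not tested apart from it.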
